A study of Homo sapiens with 15 samples.

How the data were processed

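RNA of human multiple myeloma cell lines was measured on Affymetrix Human Genome U133 Plus 2.0 arrays, with 1 array for each of 15 samples. The values are intensity, deposited by the authors as MAS5 probe set signals on a linear scale. Every array was scaled by the authors to a common 2% trimmed mean, which came to 500.1 on each array when recomputed. The MAS5 version, the probe annotation and the genome build behind it are not given in the sources used here, and no positions were used. For arrays, their number limits the precision. The table holds 54675 probe sets, of which 62 are controls. Probe sets were joined to genes through their Entrez identifiers, and 41097 of them name 1 gene, 1801 name several genes and 11777 name none. Probe sets that name several genes or none were left out.

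Samples were grouped by cell line, shRNA, drug and time as the labels give them, and 12 of the 13 OPM2 libraries form matched pairs. There are 3 pairs for lenalidomide with intact CRBN, 3 for CRBN shRNA without drug and 1 for lenalidomide in CRBN shRNA cells. The stable NT vehicle library is the control of both a lenalidomide and a CRBN shRNA pair. The stable CRBN shRNA vehicle library also serves in both kinds of pair. In the pairs, lenalidomide was compared with vehicle, or CRBN shRNA with non-targeting (NT) shRNA, at the same time and in the same experiment. Each condition has 1 library, so pairs from different times and experiments served as replicates of an effect, and p-values measure only the spread between these libraries. The 24 h lenalidomide library has no vehicle library of its own time and was left out of the tests.

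Signals were analysed as log2(signal + 15.3), the pseudocount being the 25th percentile of all values. The probe set with the highest mean over the 15 libraries stood for each gene, which gave 19775 genes. Genes were kept when their mean over the fitted libraries was at least the median over all probe sets, a signal of 48.7, which left 11859 genes in the joint fit. That fit used limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8) for reading. Its terms were lenalidomide, CRBN shRNA and their interaction, with a block for each experiment and time. It had 4 residual degrees of freedom and a prior of 9.44, and eBayes was run with a trend. The lenalidomide effect rests on 3 pairs in cells with intact CRBN, and the CRBN shRNA effect on 3 pairs without drug. The interaction compares 1 pair in CRBN shRNA cells with those 3 pairs, and the lone pair is assumed to vary like the others. Lenalidomide in CRBN shRNA cells is the sum of the lenalidomide and interaction terms. Both estimates take the baseline of these cells from the whole fit, the acute pairs included, and not from their vehicle library alone. Extra terms tested the stable against the acute CRBN shRNA effect, and the stable NT against the parental lenalidomide effect. Infected and uninfected cells were compared over 8 libraries with a term for time, 11861 genes and 3 residual degrees of freedom. Tests were two-sided, and genes passed at a Benjamini-Hochberg adjusted p under 0.05. The pair of MM1.S arrays has no replicates, so genes at least 2-fold apart were counted there without a test.

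Before the data were examined, 24 gene lists were fixed, along with the comparisons, the tests and the alternatives. Of their 357 genes, 325 have a probe set. The lists cover the CRL4-CRBN ligase, substrates of immunomodulatory drugs (IMiD substrates), the plasma cell program, MYC and ribosome biogenesis, interferon response, G1/S and DNA replication, G2/M cell cycle, CDK inhibitors, p53 targets, the unfolded protein response, ATF4 targets, cholesterol and fatty acid synthesis, NF-kB targets, adhesion and homing, WNT targets, the BCL2 family, hypoxia and glycolysis, immediate early genes, drug efflux and steroid receptor, myeloma translocation partners, and markers of B cells, T and NK cells, myeloid cells and stromal cells. Lists with at least 3 measured members were tested by limma's camera with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. For MM1.S, the median of each list was set against 10000 random lists of genes matched on expression. A further 15 gene families were chosen after the data had been seen.

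Named genes follow a rule. They are CRBN, IRF4, MYC, IKZF1, IKZF3, PRDM1, CDKN1A and CDKN1B, up to 12 higher and 12 lower genes with the smallest p among those that passed and moved the same way in every pair, and up to 4 members of each list. With fewer than 6 genes in a direction, the next smallest p were added and are named as not past the test. A sex chromosome transcript among the MM1.S genes is not reported. The text prints the fixed genes, most of those with the smallest p, and members of the lists it describes.

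The procedure was tested on simulated data, in which known changes and random noise, independent between genes, were added to fitted means. At a log2 change of 1, limma recovered 75.8% of changed genes for the lenalidomide effect, 74.2% for CRBN shRNA, 40.3% for the interaction and 56.1% for lenalidomide in CRBN shRNA cells. It recovered 22.2% for stable against acute CRBN shRNA, 31.8% for stable NT against parental lenalidomide and 46.2% for infected against uninfected cells. False calls made up 7.22% to 12.7% of the calls. A list of 15 genes shifted by 0.25 was called in 20 of 20 rounds, and 1 of 460 unshifted lists was called. These lists were drawn at random, so their genes were not correlated. This rate therefore says nothing about lists of correlated genes, such as the ATF4 targets with an estimated correlation of 0.70. Alternatives were another pseudocount, no filter or a stricter filter, quantile normalization, median centring, all probe sets tested separately, eBayes without a trend, no block, fits of the matched pairs alone, other fold thresholds and leaving out each library in turn. Of these, 3 were chosen after seeing the data: the CRBN shRNA effect without the acute 72 h pair, the lenalidomide effect without the parental 72 h pair, and the infected and uninfected libraries compared at each time. Plots were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.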

Results

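Gene expression was measured in 2 multiple myeloma cell lines, MM1.S and OPM2, with 1 array per sample and 15 samples in all. MM1.S gave 1 parental and 1 lenalidomide-resistant sample. OPM2 cells infected with lentivirus carrying CRBN shRNA or non-targeting (NT) shRNA were sampled at 48 h and 72 h, which gave 4 samples. Cells stably expressing either shRNA were treated with lenalidomide or vehicle for 48 h, which gave 4 more. The labels give the stable CRBN shRNA cells as resistant and the stable NT cells as sensitive to lenalidomide. Uninfected OPM2 cells, here called parental, received vehicle for 48 h or 72 h, or 30 µM lenalidomide for 24 h, 48 h or 72 h. The sample titles give the stable cells as sorted. The marker sorted on and the lenalidomide dose of these cells are not given in the sources used here. Median signal per array ran from 48.5 to 65.3. It was higher after lenalidomide in cells with intact CRBN, at 65.3 against 52.7 with vehicle at 48 h, 61.1 against 52.5 at 72 h, and 64.1 against 56.9 in stable NT cells. In stable CRBN shRNA cells it was 57.9 with lenalidomide and 59.6 with vehicle. A gap also arose without drug. In the infected cells at 72 h the median was 63.2 with CRBN shRNA and 48.5 with NT, and at 48 h 58.4 and 57.7. The 3'/5' signal ratio of actin, used as a measure of RNA integrity, was 20.7 to 30.0 in parental cells at 48 h and 72 h and in the infected cells at 48 h. It was 6.49 and 7.00 in the infected cells at 72 h, 4.10 to 5.22 in stable cells, 14.9 in parental MM1.S and 10.2 in resistant MM1.S. The same ratio of GAPDH was 0.94 to 1.19 over the 15 arrays, so the actin ratio alone does not show how intact the RNA was.

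CRBN encodes cereblon, the protein that lenalidomide binds and the substrate receptor of a CRL4 ubiquitin ligase. The arrays give its RNA level in each sample, while cereblon protein was not measured. In resistant MM1.S the CRBN signal was 100.2 against 2408 in parental cells, 4.16% of the parental level, and 154 against 1348, or 11.4%, for the other CRBN probe set. With CRBN shRNA in OPM2, the signal of the same probe set was 50.7% of NT at 48 h, 45.8% at 72 h and 69.4% in the stable cells. Over those 3 pairs CRBN fell by 1.80-fold (log2 -0.85 ± 0.13 SE; limma adjusted p = 0.00993, within 0.00268 to 0.430 over the alternatives). Lenalidomide itself gave a CRBN difference of 0.24 ± 0.13 over 3 pairs, which did not pass (adjusted p = 0.196). The other CRBN probe set gave 72.0%, 47.5% and 75.7% of NT in the same order, and a CRBN shRNA difference of -0.64 that did not pass (adjusted p = 0.105). Without 1 of the acute libraries CRBN did not pass either, with adjusted p = 0.144 without NT 48 h, 0.140 without CRBN shRNA 48 h, 0.162 without NT 72 h and 0.161 without CRBN shRNA 72 h.

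**Figure D1:**
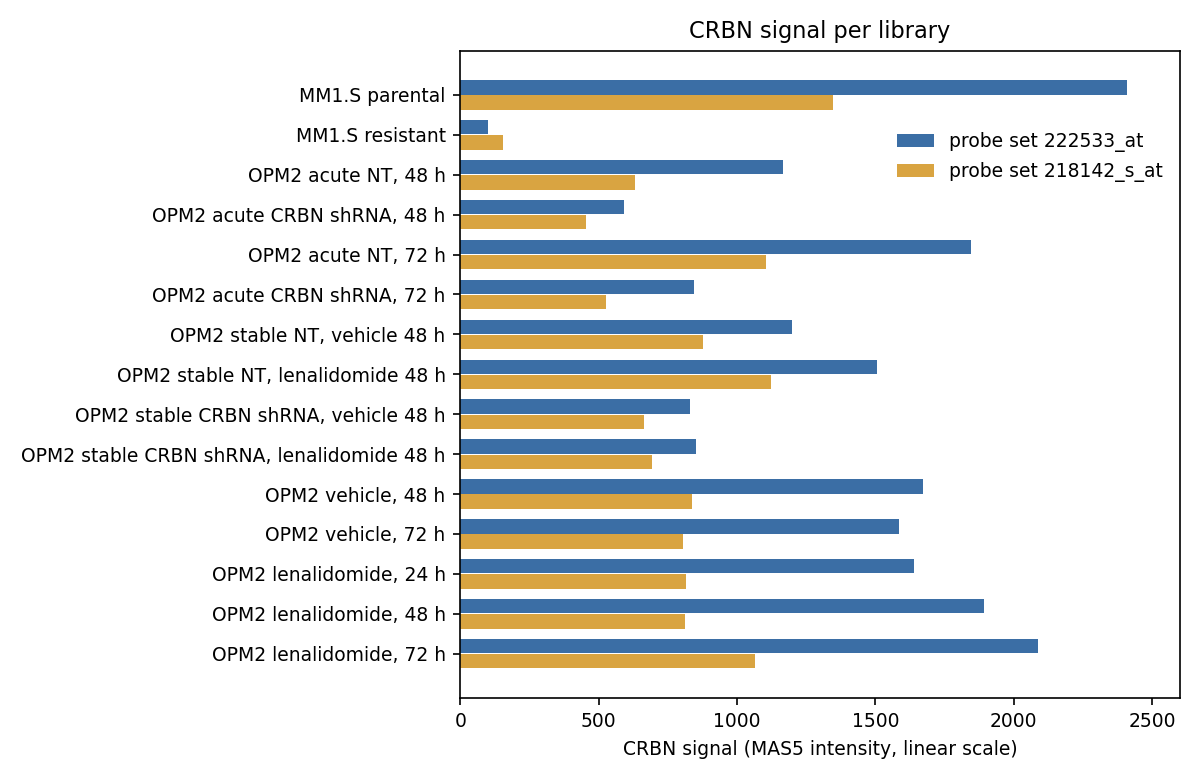
Bars give the CRBN signal (linear MAS5 signal, x axis from 0) of each of the 15 libraries (y axis, 1 array each, no error bars) for both CRBN probe sets, blue for the one used in the tests and yellow for the other. In blue, resistant MM1.S lies at 100.2 and parental MM1.S at 2408, and each CRBN shRNA library lies below its NT partner.

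The comparison of lenalidomide with vehicle asks what the drug does to gene expression in OPM2 cells with intact CRBN. Of the genes named here, 2 interferon-stimulated genes rose most: IFIT3, an antiviral effector, rose 81.6-fold (log2 6.35 ± 0.29 SE over 3 pairs; adjusted p = 9.25e-08) and IFI27 rose at least 35.8-fold in each pair (5.90 ± 0.35; adjusted p = 2.32e-07). Vehicle signals of IFI27 were 18.6 to 63.2, so this bound counts those under 48.7 as 48.7, and its log2 value depends on the pseudocount. MYC, the growth-promoting transcription factor, fell 4.40-fold (-2.14 ± 0.18; adjusted p = 2.81e-06), and the cell cycle inhibitor CDKN1A (p21) rose 5.96-fold (2.57 ± 0.17; adjusted p = 7.13e-07). GADD45A, a growth arrest gene, rose 4.73-fold (2.24 ± 0.11). In all, 3622 of 11859 genes passed, 1897 higher and 1725 lower, and 3572 of them moved the same way in all 3 pairs. Of these genes, 530 were at least 2-fold higher and 207 at least 2-fold lower. Genes were called in the same 3 pairs, so their shared direction is not independent of the choice.

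Other genes with the smallest p among those that rose were SPRR3 (4.20) and SPRR2B (3.18), proteins of the cornified envelope of epithelia, the transcription factors KLF4 (2.78) and ETS1 (2.02), the guanine nucleotide exchange factor gene DOCK4 (2.93), the caveolin CAV2 (2.20), NMRK1 (2.06), CITED2 (2.05) and TRAF3IP3 (1.82). Genes that fell included SLC25A15 (-1.74), an ornithine carrier of mitochondria, TRAP1 (-1.53), a chaperone of the HSP90 family, ME2 (-1.44), a malic enzyme, OMA1 (-1.60), a protease, and SFXN4 (-1.29). SRM (-1.41), spermidine synthase, NPM3 (-1.56), HPDL (-1.92) and the phosphodiesterase PDE4A (-1.79) also fell. Among the lymphoid transcription factors named beforehand, IKZF3 rose by 0.66, PRDM1 by 0.51 and IKZF1 by 0.36, while IRF4 gave 0.08 and did not pass (adjusted p = 0.696).

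Of the 22 measured interferon response genes 19 rose and 0 fell, with a median of 1.78, and 20 rose and 1 fell adjusted over the list alone. IFI6, with vehicle signals down to 17.0, rose at least 11.0-fold in each pair on the same terms, and IFITM1 rose by 2.75. The list's camera adjusted p was 6.62e-11, and adjusted p = 0.278 with an estimated correlation. Of the 16 MYC and ribosome biogenesis genes, which serve cell growth, 14 fell and 0 rose, with a median of -0.85, and 15 fell adjusted over the list alone (camera adjusted p = 5.67e-09, and adjusted p = 0.278 with an estimated correlation). NOP16 gave -1.15 and POLR1B -1.23. Of the 21 G1/S and DNA replication genes 14 fell and 0 rose, with a median of -0.45, and 16 fell adjusted over the list alone (camera adjusted p = 0.000203, and adjusted p = 0.512 with an estimated correlation). CDC45 gave -0.79 and MCM2 -0.60, both parts of the replicative helicase.

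Of the 6 CDK inhibitors 4 rose and 0 fell, by both adjustments, the second being adjusted over the list alone. CDKN1C gave 1.85, CDKN2B 1.13 and CDKN1B 0.59, with a list median of 0.86 (camera adjusted p = 0.0173, and adjusted p = 0.458 with an estimated correlation). Immediate early genes had 7 of 11 higher and 0 lower, also when adjusted over the list alone, with KLF6 at 0.87 and JUN at 0.76 (camera adjusted p = 0.00854, and adjusted p = 0.278 with an estimated correlation). In the adhesion and homing list 6 of 12 rose and 1 fell, or 7 and 1 adjusted over the list alone, with the integrins ITGB7 at 0.97 and ITGB1 at 0.91 and the P-selectin ligand SELPLG at 1.30 (camera adjusted p = 0.0173, and adjusted p = 0.458 with an estimated correlation). None of these 6 lists passed with an estimated correlation. The power of that form, with 4 residual degrees of freedom, was not measured, so a miss there does not show that a list is unshifted. Estimated correlations were 0.12 for interferon response, 0.25 for MYC and ribosome biogenesis and 0.46 for G1/S genes. They were 0.32 for CDK inhibitors, 0.12 for adhesion and homing and -0.04 for immediate early genes. Where members vary together more than the preset 0.01, the preset form gives p-values that are too small.

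The other 16 lists tested did not pass camera. Of 8 B cell markers 5 rose and 0 fell, among them BLNK (3.15), an adaptor of B cell receptor signalling, and CD74 (1.33) and HLA-DRA (0.996), which belong to MHC class II antigen presentation. Of 15 plasma cell program genes 4 rose and 3 fell, with CD38 at 1.13, SLAMF7 at -1.81 and MZB1 at -1.02, and the list's median of 0.08 has the opposite sign to its mean of -0.08 and its test. Of 7 myeloma translocation partners 5 rose and 1 fell, with MAF at 1.63 and FGFR3 at -1.26. Of 7 IMiD substrates 2 rose and 1 fell, with GSPT1, a translation termination factor, at -0.52. Rising and falling members numbered 3 and 1 of 15 p53 targets, 4 and 0 of 17 unfolded protein response genes, 3 and 0 of 9 NF-kB targets, and 3 and 2 of 11 BCL2 family genes, where the pro-apoptotic BCL2L11 rose by 1.16. They were 2 and 4 of 14 hypoxia and glycolysis genes, whose mean of 0.09 has the opposite sign to the median of -0.05 and the test, 2 and 4 of 6 drug efflux and steroid receptor genes, and 0 and 0 of 4 stromal markers. For these 11 lists the counts adjusted over the list alone were the same. Of 15 cholesterol and fatty acid synthesis genes 0 rose and 6 fell (1 and 7 adjusted over the list alone), of 22 G2/M genes 0 and 4 (0 and 2), of 17 ATF4 targets 1 and 3 (1 and 0), of 7 WNT targets 2 and 2 (3 and 2) and of 8 CRL4-CRBN ligase genes 1 and 0 (0 and 0). T and NK cell markers and myeloid markers had fewer than 3 members above the filter and were not tested.

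Leaving out 1 library moved the lenalidomide count beyond 1.5-fold only for the parental 72 h libraries, with 2362 genes without vehicle and 2336 without lenalidomide. Median centring moved the median of all genes from 0.05 to -0.15 and the split to 1054 higher and 2940 lower genes, so the share of lower genes was 73.6% against 47.6% as deposited.

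**Figure D2:**
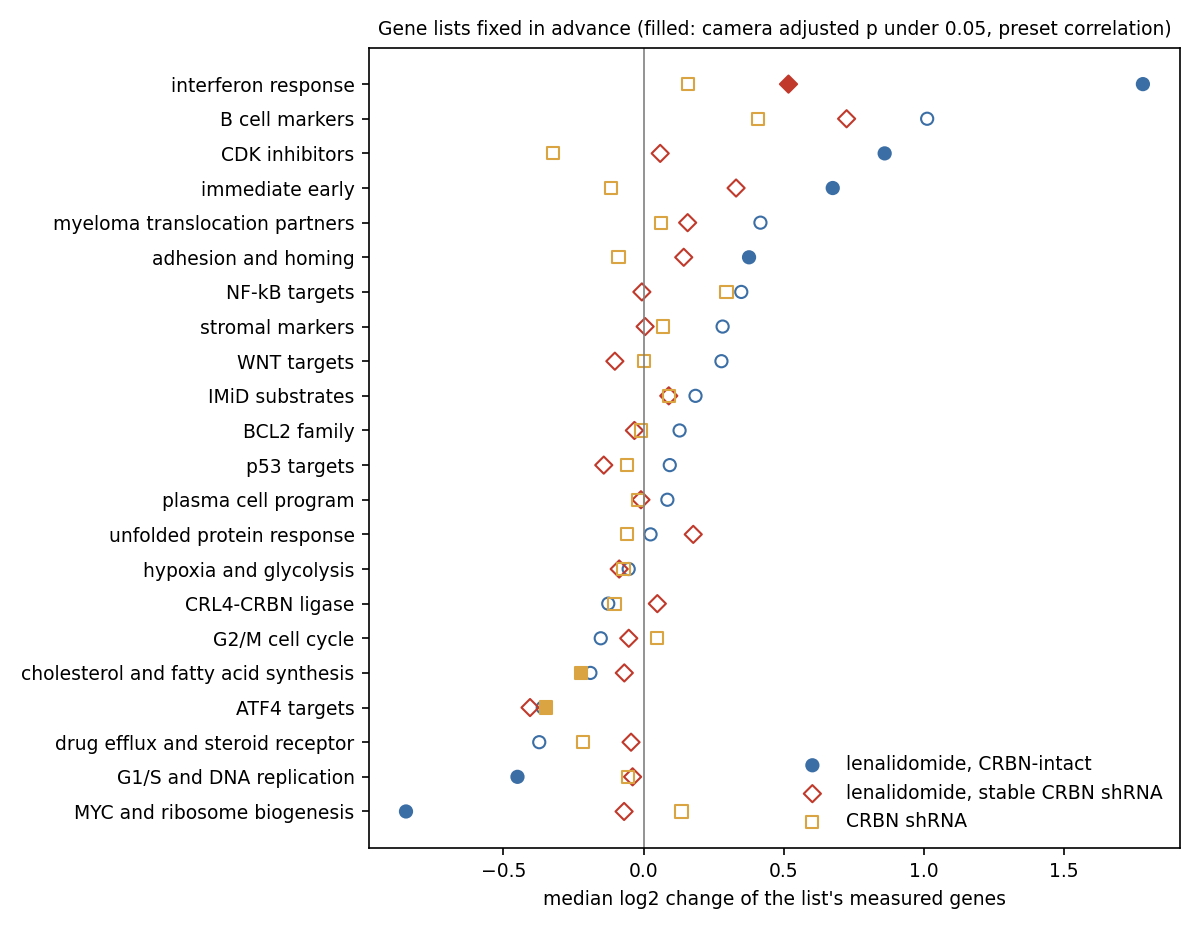
Points give the median log2 change of each gene list (x axis; y axis, 1 list per line) for lenalidomide in CRBN-intact cells (circles), lenalidomide in stable CRBN shRNA cells (diamonds) and CRBN shRNA (squares), filled where camera with the preset correlation passed, while none passed with an estimated correlation. The interferon response list lies at 1.78 in CRBN-intact and at 0.52 in CRBN shRNA cells, and the MYC and ribosome biogenesis list at -0.85 in CRBN-intact cells.

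CRBN shRNA was compared with NT shRNA in cells without drug. The sample titles give all CRBN shRNA libraries, acute and stable, the same shRNA number. The 3 pairs therefore cannot separate loss of CRBN from an off-target effect of that shRNA. Fewer genes passed than after lenalidomide, and most were lower: 74 of 87 fell and 13 rose. All 87 moved the same way in the 3 pairs, but they were chosen in these pairs, so this is not independent of the choice. Across 11990 genes, 58.2% had the same sign in the acute pairs at 48 h and 72 h. The wider set of 1387 genes at an unadjusted p under 0.05 had another balance, with 738 higher and 649 lower. Besides CRBN, the genes that fell included RAB2B, a small GTPase (-1.27 ± 0.15 SE; adjusted p = 0.00314), CKS1B, a regulatory subunit of cyclin-dependent kinases (-1.04 ± 0.12; adjusted p = 0.00314), the nucleoporin NUP43 (-1.35 ± 0.18; adjusted p = 0.00383) and the integrin ITGA4 (-0.70 ± 0.13; adjusted p = 0.0234). TULP3 rose most clearly (1.28 ± 0.16; adjusted p = 0.00314), followed by CD74, the invariant chain of MHC class II (0.87 ± 0.13; adjusted p = 0.00829). In the acute experiments the NT cells themselves had low CD74, at -2.08 at 48 h and -2.65 at 72 h against uninfected vehicle cells. Also lower were LONRF1 (-1.24), PTTG1IP (-1.14), TMEM30A (-1.12), ERLIN1 (-1.03), CCM2 (-0.97), SUCO (-0.90), SYPL1 (-0.89) and COA1 (-0.77), and also higher were TTC39C (0.92), the microRNA-processing enzyme DICER1 (0.85), the chromatin remodeller CHD7 (0.73) and LIFR (0.64). MYC gave 0.06 (adjusted p = 0.929), IRF4 -0.21 (adjusted p = 0.599) and CDKN1A -0.48 (adjusted p = 0.287), none past the test. IKZF1 gave -0.16, IKZF3 0.23, PRDM1 0.03 and CDKN1B 0.19, which did not pass either.

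Of the 15 cholesterol and fatty acid synthesis genes, 13 were below NT with a median of -0.22, and none passed alone, also when adjusted over the list alone (camera adjusted p = 0.0146, and adjusted p = 0.583 with an estimated correlation). SQLE, an enzyme of cholesterol synthesis, gave -0.39. Of the 17 ATF4 targets, which respond to amino acid shortage and stress, 16 were below NT with a median of -0.35, and none passed alone or adjusted over the list alone (camera adjusted p = 0.046, and adjusted p = 0.711 with an estimated correlation). SLC7A11 gave -0.86 and DDIT4 -0.57. The ATF4 call was lost without NT 48 h (camera adjusted p = 0.101), CRBN shRNA 48 h (0.0996), stable CRBN shRNA vehicle (0.299) or stable NT vehicle (0.714, with a median of 0.07), with the pseudocount at the 5th percentile (0.0535), without a filter on low values (0.101) and under median centring (0.0891). The cholesterol call was lost without NT 72 h (camera adjusted p = 0.395) or CRBN shRNA 72 h (0.394). Median centring moved the median of all genes from 0.03 to -0.10 and gave 10 higher and 168 lower genes, 94.4% lower against 85.1% as deposited.

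The CRBN shRNA count rests on the acute libraries: it was 1 without NT 48 h, 2 without CRBN shRNA 48 h and 0 by limma without NT 72 h or CRBN shRNA 72 h (876 and 881 genes at an unadjusted p under 0.05), against 133 without stable NT vehicle and 55 without parental lenalidomide 48 h. It rests on the model too: with all libraries limma called 0 genes by eBayes without a trend and 0 with no block (1201 and 595 at an unadjusted p under 0.05). The acute 72 h CRBN shRNA array had an 18S ribosomal RNA signal of 32065 against 14067 on its NT partner. Its median signal was 63.2 against 48.5. Without this pair limma called 0 genes (882 at an unadjusted p under 0.05).

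The interaction asks whether lenalidomide acts differently once CRBN is reduced, by setting 1 pair of stable CRBN shRNA cells against the 3 pairs with intact CRBN. In the fit, the baseline of the CRBN shRNA cells also draws on the acute pairs. ARG2, CDKN1A, IFI27 and TRAP1 were among the genes whose response was smaller in the CRBN shRNA pair. ARG2, a mitochondrial arginase, gave 2.27, 1.80 and 2.28 in the intact pairs and -0.09 in the CRBN shRNA pair, a difference of -2.32 ± 0.29 SE (adjusted p = 0.0126). For CDKN1A the values were 2.18, 3.13 and 2.28 against 0.81 (-1.90 ± 0.31; adjusted p = 0.0333), and for IFI27 4.78, 6.16 and 6.72 against 1.51 (-4.42 ± 0.62; adjusted p = 0.0126). TRAP1, which fell in intact cells, gave -0.33 in the CRBN shRNA pair (difference 1.25 ± 0.17; adjusted p = 0.0126). In all, 45 genes passed, 20 with a positive and 25 with a negative difference. In each of the 45 the CRBN shRNA pair lay outside the range of the intact pairs. These pairs also served to choose the genes, so this is not independent of the choice. The values of IFI27 depend on the pseudocount, as do those of LAPTM5, a lysosomal membrane protein of blood cells (difference -3.95), whose vehicle signals in intact cells were 6.58, 44.9 and 24.2 and whose call was lost with the pseudocount at the 5th percentile. The difference for MYC was 1.54 and missed the threshold (adjusted p = 0.0524), as did that of the interferon-stimulated gene ISG15 (-2.44; adjusted p = 0.0524).

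By list, 15 of 16 MYC and ribosome biogenesis genes had a positive difference, with a median of 0.82, 2 past the test and 9 adjusted over the list alone (camera adjusted p = 9.19e-10, and adjusted p = 0.356 with an estimated correlation). Of the 22 interferon response genes 21 had a negative difference, with a median of -1.20, 1 past the test and 11 adjusted over the list alone (camera adjusted p = 9.19e-10, and adjusted p = 0.356 with an estimated correlation). All 21 G1/S genes had a positive difference, with a median of 0.37 and 0 past the limma test, also adjusted over the list alone (1855 of all genes had an unadjusted p under 0.05; camera adjusted p = 0.00019, and adjusted p = 0.627 with an estimated correlation). All 6 CDK inhibitors had a negative difference, with a median of -0.87, 1 past the test and 4 adjusted over the list alone (camera adjusted p = 0.028, and adjusted p = 0.627 with an estimated correlation). The CDK inhibitor call was lost without acute NT 48 h (camera adjusted p = 0.0619), CRBN shRNA 48 h (0.0613), NT 72 h (0.0552), CRBN shRNA 72 h (0.0561) or stable NT lenalidomide (0.110). The difference for CRBN itself was -0.01 (adjusted p = 0.990).

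The interaction count was 4 without acute NT 48 h, 7 without acute CRBN shRNA 48 h, 0 without either acute 72 h library (1514 without NT and 1511 without CRBN shRNA at an unadjusted p under 0.05), 269 without stable CRBN shRNA vehicle, 339 without stable NT vehicle, 24 without stable NT lenalidomide, 19 and 14 without vehicle 48 h and 72 h, and 17 and 13 without lenalidomide 48 h and 72 h. It was 25, 10 of them among the 45, against the stable NT pair alone, whose dose like that of the CRBN shRNA pair is not given while the parental pairs had 30 µM, and median centring, which moved the median of all genes from -0.07 to 0.18, gave 477 genes, 419 with a positive and 58 with a negative difference.

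**Figure D3:**
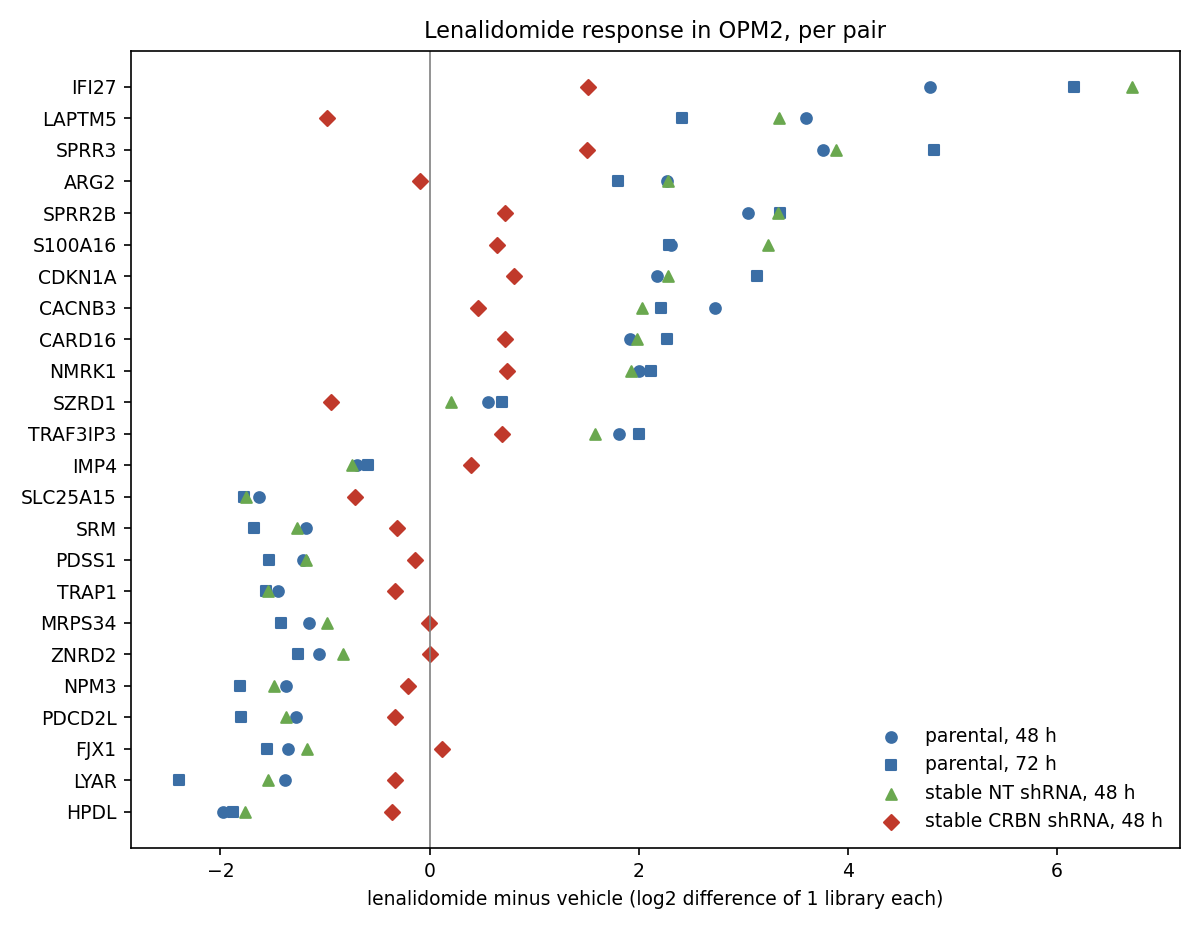
Points give the log2 change after lenalidomide (x axis) in each of the 4 pairs (parental 48 h and 72 h, stable NT, and stable CRBN shRNA as red diamonds) for 24 genes whose response differed (y axis, 1 gene per line). ARG2 lies at 2.27, 1.80 and 2.28 in the pairs with intact CRBN and at -0.09 in the stable CRBN shRNA pair, and the values of IFI27 and LAPTM5, with signals under 48.7, depend on the pseudocount.

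For the stable CRBN shRNA cells, the lenalidomide effect of the joint fit asks which responses were left. Its baseline also draws on the acute pairs and the stable NT libraries, and its SE on the spread of the other pairs. CRBN, for example, gave 0.22 in the fit and 0.035 in the stable CRBN shRNA pair itself. IFIT3 rose 16.1-fold (4.01 ± 0.47 SE, 1 lenalidomide library; adjusted p = 0.00558), and GADD45A rose as well (1.56 ± 0.18; adjusted p = 0.00558). Higher too were the antiviral gene DDX60L (2.46), NDRG1 (1.98), the transcription factors WT1 (1.70), KLF4 (1.52) and ETS1 (1.23), and INAFM2 (1.33), while SMIM27 fell (-1.31). These are the 9 genes that passed. Of all genes 587 had an unadjusted p under 0.05, where 593 would pass by chance, so this count shows no excess over chance. Not past the test were CDKN1A (0.68; adjusted p = 0.941), IFI27 (1.48; adjusted p = 0.832), MYC (-0.60), CRBN (0.22), BCL11A (-1.05; adjusted p = 0.114) and TFDP2 (-1.58). Of the 22 interferon response genes 18 were higher, with a median of 0.52, and 1 passed, also adjusted over the list alone (camera adjusted p = 1.02e-05, and adjusted p = 0.472 with an estimated correlation), a call lost without stable CRBN shRNA vehicle (camera adjusted p = 0.076). The gene count was 3 without each of the 4 acute libraries, vehicle 48 h or lenalidomide 48 h, 1 without stable CRBN shRNA vehicle, 16 without stable NT vehicle and 19 without stable NT lenalidomide. Quantile normalization gave 6 higher and 0 lower genes.

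Effects were also compared between experiments: CRBN shRNA in stable against acutely infected cells, and lenalidomide in stable NT against uninfected parental cells, where the dose of the former is not given in the sources used here. For CRBN shRNA, limma called 0 genes (698 at an unadjusted p under 0.05, where 593 would pass by chance), and the smallest p were those of the protease inhibitor SLPI (1.76) and the selenium carrier SELENOP (-1.73), both at adjusted p = 0.179. CRBN gave 0.51 (adjusted p = 0.839). For lenalidomide, 4 genes had a more negative log2 change in stable NT than in parental cells, each at adjusted p = 0.0323: the surface receptor SLAMF7 (-1.46 ± 0.20 SE), the amino acid transporter SLC7A5 (-1.65 ± 0.24), RELN (-1.69 ± 0.25) and ASS1 (-2.03 ± 0.30), an enzyme of arginine synthesis. In stable NT cells SLAMF7 gave -2.73, against -1.22 and -1.31 in the parental pairs, SLC7A5 -2.82 against -0.98 and -1.09, RELN -2.04 against -0.17 and -0.19, and ASS1 -2.03 against 0.06 and 0.41. MYC gave -1.03 and did not pass (adjusted p = 0.229). The count of 4 became 0 by limma without any of the 4 acute or the 4 parental libraries (470 to 983 genes at an unadjusted p under 0.05), 49 without stable CRBN shRNA vehicle and 1 without stable NT vehicle, and median centring gave 3 higher and 13 lower genes. The count of 0 for CRBN shRNA became 1 without stable NT vehicle and 10 without stable NT lenalidomide.

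Infected NT and uninfected vehicle cells at 48 h and 72 h were compared for what infection itself brings, although virus and day of work cannot be told apart in this design. Of 14 MHC class II genes, which present antigen and were grouped after the data were seen, 9 fell and 12 had negative values (median -1.66; 11 fell adjusted over the list alone; camera adjusted p = 1.7e-10, and adjusted p = 0.565 with an estimated correlation). CIITA, their transcriptional activator, gave 0.24 at 48 h and 0.53 at 72 h, and HLA-DOA 1.69 and -0.11. CD74 fell 5.14-fold (-2.36 ± 0.21 SE over 2 times; adjusted p = 0.00217), HLA-DRB4 fell at least 10.7-fold at each time, with infected signals of 29.8 and 41.8 counted as 48.7, HLA-DQA1 gave -2.47, HLA-DRB1 -2.32, HLA-DPA1 -2.24 and HLA-DPB1 -2.03. SLPI fell (-2.92 ± 0.24; adjusted p = 0.00217), as did CASP1 (-1.78), the inflammatory caspase, and GNG10 (-2.39). Higher in infected cells were the transcription factor KLF2 (1.95 ± 0.17; adjusted p = 0.00217), the p53 target TP53INP1 (2.74), steroid sulfatase STS (2.38) and the hypoxia-induced transcript MIR210HG (2.39). In all, 40 genes passed, 22 higher and 18 lower. All 40 moved the same way at both times, with 35 at least 2-fold apart at 48 h and 40 at 72 h. Both times entered the choice of these genes, so this agreement is not independent of it. The actin ratio was 25.1 on the infected and 26.5 on the vehicle array at 48 h, and 6.49 and 20.7 at 72 h. MYC gave 1.40 (adjusted p = 0.147), CDKN1A 1.20 (adjusted p = 0.134) and CRBN -0.15 (adjusted p = 0.762), none past the test.

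Camera called 10 of the lists fixed beforehand in this comparison, and none passed with an estimated correlation, where the adjusted p ran from 0.569 to 0.612. Higher in infected cells were immediate early genes (median 1.03, 1 gene past the test and 8 adjusted over the list alone; camera adjusted p = 1.83e-06), cholesterol and fatty acid synthesis (0.63, 0 and 7; adjusted p = 0.0011), p53 targets (0.38, 1 and 3; adjusted p = 0.0057) and CDK inhibitors (0.69, 0 past the test, 4 higher and 1 lower adjusted over the list alone; adjusted p = 0.0408). NF-kB targets (0.46, 0 and 2; adjusted p = 0.00995), ATF4 targets (0.39, 0 by both adjustments; adjusted p = 0.0214) and hypoxia and glycolysis genes (0.21, 7 of 14 higher, 1 past the test, 5 higher and 1 lower adjusted over the list alone; adjusted p = 0.0214) were also called as higher. Lower were MYC and ribosome biogenesis (-0.48, 0 past the test, 1 higher and 6 lower adjusted over the list alone; adjusted p = 0.00478), G1/S genes (-0.35, 0 and 2; adjusted p = 0.00995) and B cell markers, which hold MHC class II genes (-0.60, 3 fell, 1 higher and 4 lower adjusted over the list alone; adjusted p = 0.0438). The immediate early call held in each of the 14 refits by scaling, filter, pseudocount and library left out. Without acute NT 72 h, calls were lost for MYC and ribosome biogenesis (camera adjusted p = 0.0687), p53 targets (0.0687), CDK inhibitors (0.0875), ATF4 targets (0.445) and B cell markers (0.062). Without vehicle 72 h they were lost for these same 5 lists (0.177, 0.177, 0.177, 0.963 and 0.164, with a median of -0.16 for ATF4 targets), G1/S genes (0.391) and NF-kB targets (0.061). Without vehicle 48 h they were lost for cholesterol and fatty acid synthesis (0.0506), hypoxia and glycolysis (0.13) and B cell markers (0.0506), and without acute NT 48 h for G1/S genes (0.173). The CDK inhibitor call was also lost without lenalidomide 48 h or 72 h (0.0509 and 0.0508), and that of B cell markers without acute CRBN shRNA 48 h or 72 h (0.0511 and 0.0512), with the pseudocount at the 5th percentile (0.0544) and without a filter (0.0708). With the filter at the 75th percentile CDK inhibitors and hypoxia and glycolysis were lost (both 0.0903), and the median of the latter was -0.0395. The gene count was 25 without acute NT 48 h, 1 without acute NT 72 h, 66 and 8 without vehicle 48 h and 72 h, and 18 without lenalidomide 48 h or 72 h.

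Resistant and parental MM1.S were compared to find what differs in a lenalidomide-resistant line derived from MM1.S, as values with no replicates and no test. Among 12381 genes, 532 were at least 2-fold higher and 670 at least 2-fold lower in resistant cells. Lower in resistant cells besides CRBN (-4.39) were ASS1 (-4.90), GPAT3 (-4.80), an acyltransferase of lipid synthesis, and DDIT4 (-4.08), an inhibitor of mTOR signalling. Higher were TMPRSS15 (3.67) and SCD (2.92), a fatty acid desaturase. Where a signal lay under 48.7, near background, it was counted as 48.7: LILRA2, an immunoglobulin-like receptor, was then at least 29.8-fold, RFLNB at least 10.4-fold and ADAMTS2 at least 6.27-fold higher, and THEMIS at least 19.1-fold and FUCA2, a secreted fucosidase, at least 16.5-fold lower. MYC and CDKN1A each gave -1.03, IKZF1 0.27, IKZF3 0.13, IRF4 0.13, PRDM1 0.11 and CDKN1B -0.08.

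Of the 17 ATF4 targets 13 were at least 2-fold lower, with a median of -1.18, below all random lists (percentile 0). Random lists were drawn gene by gene, so a list whose members vary together can reach an extreme percentile. The percentiles in this part are therefore no test. DDIT3, a stress-induced transcription factor, gave -2.33, and CTH, an enzyme of cysteine synthesis, -2.52. Of the 15 cholesterol and fatty acid synthesis genes 6 were at least 2-fold higher, with a median of 0.90 (percentile 100), including INSIG1 at 1.65 and DHCR7 at 1.32, and of the 22 G2/M genes 5 were, with a median of 0.67 (percentile 100) and BIRC5 at 1.40. Medians were low for MYC and ribosome biogenesis (-0.40, percentile 0.01), with 1 of 16 genes at least 2-fold lower, immediate early genes (-0.73, percentile 0.025), with 0 of 9, and CDK inhibitors (-0.55, percentile 2.16), with 2 of 4. They were also low for p53 targets (-0.39, percentile 0.22), with 3 of 15 at least 2-fold lower and 1 higher, and for drug efflux and steroid receptor genes (-0.70, percentile 0.225), with 3 of 7 lower. The interferon response list had a median of 0.15 (percentile 91.6).

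Effects were also set against each other across 11990 genes, which are not independent replicates, in 10 pairs of effects with no p-value. The lenalidomide effect in parental cells and the acute CRBN shRNA effect, which share no library, had a Pearson correlation of 0.0657 and a Spearman correlation of 0.0849, and 53.3% of genes had the same sign. Within each time the Pearson correlation was 0.0518 at 48 h and 0.0284 at 72 h. The lenalidomide effect of parental cells had a correlation of 0.611 with that of stable NT cells and of 0.354 with that of stable CRBN shRNA cells, and the 48 h and 72 h effects one of 0.590. The CRBN shRNA effects at 48 h and 72 h had a correlation of 0.141, and the acute and stable effects one of 0.153. With MM1.S resistant minus parental, the correlation was -0.0271 for lenalidomide and 0.0361 for acute CRBN shRNA.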

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

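The tests of the lenalidomide response left in stable CRBN shRNA cells and of the genes with the smallest p without the acute 72 h CRBN shRNA array were chosen only after the result was seen, as were the family of MHC class II genes, its comparison at each time between infected and uninfected cells, for which the bounds were written before the values at each time were seen, and the 24 h values of genes chosen in the stable NT pair, and the other tests in this part were written before.

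The lenalidomide response differed by test between CRBN shRNA and CRBN-intact OPM2 for 45 genes. The differences (log2) were -2.32 for ARG2, -2.82 for SPRR3, -2.28 for SPRR2B, -1.46 for NMRK1, -4.42 for IFI27, -1.90 for CDKN1A, -2.15 for S100A16, -1.17 for TRAF3IP3, -1.52 for CARD16, -1.86 for CACNB3, -3.95 for LAPTM5 and -1.44 for SZRD1, where those of IFI27 and LAPTM5 depend on the pseudocount. They were 1.25 for TRAP1, 1.71 for HPDL, 1.36 for NPM3, 1.33 for MRPS34, 1.10 for SLC25A15, 1.24 for PDSS1, 1.20 for SRM, 1.55 for FJX1, 1.33 for ZNRD2, 1.60 for LYAR, 1.005 for IMP4 and 1.42 for PDCD2L. The lenalidomide effect differed by test between stable NT and parental OPM2 for 4 genes, at -1.46 for SLAMF7, -1.65 for SLC7A5, -1.69 for RELN and -2.03 for ASS1.

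The 24 h lenalidomide library, which no test used, also held a signal above the vehicle libraries. Of the 530 genes at least 2-fold higher after lenalidomide, 508 lay above the mean of the vehicle libraries at 24 h, and the interferon response list had a median of 1.03. Those genes were chosen against the same vehicle libraries, so the count of 508 is not independent of the choice. Of 629 genes at least 2-fold higher in the stable NT pair, which shares no library with this difference, 83.8% lay above the vehicle mean at 24 h, against 51.9% of all 11859 genes. No vehicle was taken at 24 h, so this difference was not tested.

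Splits of the libraries were counted for both effects. For lenalidomide, 1 of the 10 splits of the 6 libraries gave at least as many genes as the real 3622, which was the real split, and the highest other split gave 0. For CRBN shRNA 1 of 10 gave at least the real 87, again the real split, and the highest other split gave 10. With 10 splits no share under 0.05 can be reached.

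Among the 87 genes called for CRBN shRNA 74 were lower, while of the 1387 at an unadjusted p under 0.05, 738 were higher and 649 lower. Of the 86 called genes other than CRBN, 51.2% had the same sign in resistant minus parental MM1.S, a share at percentile 58.2 of random gene sets matched on expression, between their median of 50% and their 95th percentile of 58.2%. Loss of CRBN itself and an off-target effect of the shRNA therefore cannot be told apart here, since MM1.S is another line with 1 array per group. Of the 87 genes with the smallest p in a fit without the acute 72 h CRBN shRNA array, 61 of them among the called genes, 87.4% were lower (95% Wilson interval 78.8% to 92.8%, taking genes as independent), against 85.1% with it, which argues against the quality of that array as the source of the excess. Among genes at an unadjusted p under 0.05 the share was 59.1% without the array and 46.8% with it, which decides nothing since no excess is there with the array, and limma called 0 genes without it (881 at an unadjusted p under 0.05).

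A smaller lenalidomide response was left in the stable CRBN shRNA cells. Of 552 genes chosen in the parental pairs, 85.3% had the same sign in the stable CRBN shRNA pair, against a bound of at most 60% for array noise alone, which argues against noise as the whole cause. The response as a share of that in stable NT cells had a median of 0.276 for higher and 0.438 for lower genes, and a share of cells with intact CRBN among the stable cells would make these equal. The difference was -0.162 (95% bootstrap interval -0.236 to -0.105), -0.135 (-0.195 to -0.0654) under quantile normalization and -0.0304 (-0.0725 to 0.0377) under median centring, so the scaling decides whether it holds 0. A mixture of cells and a weaker response in every cell therefore cannot be told apart, although the titles give the stable cells as sorted. A sort for the vector, whose marker is not given in the sources used here, would remove uninfected cells. A weaker response in every cell may follow from the CRBN RNA left at 69.4% of NT, or 75.7% by the other probe set. Cereblon protein was not measured.

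Of 14 MHC class II genes 12 were lower in NT infected than in uninfected cells, as were 72 of 76 genes of the mitochondrial ribosome and 51 of 55 of the cytosolic ribosome, the latter not under quantile normalization. An array batch seen in the hybridization controls would spare the 48 h pair, whose controls are alike, yet its median difference was -1.61 with 12 of 14 genes lower, which argues against that batch as the whole cause. A lasting effect of the NT lentivirus would lower them in stable NT cells too, where stable NT minus parental cells at 48 h gave a median of 0.19 with vehicle, with 4 of 14 genes lower, and of 0.80 with lenalidomide, with 1 of 14 lower. Those arrays come from different experiments and differ in the bioB hybridization control (672 against 1705 with vehicle) and in the actin ratio (5.22 against 26.5), so the bound of -0.5 set beforehand was wrong for this design, and a lasting effect offset by a difference between experiments cannot be told apart from none. A passing effect of infection and a difference between days of work also stay open and were not tested.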

How the results depend on the processing

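Among the tests, those without the acute 72 h pair, without the parental 72 h pair and with infected and uninfected cells compared at each time were chosen only after the result was seen. Of 3807 values for 188 named results 3070 kept their direction and their side of the threshold, and 651 lost their call. Another 26 gained one, 60 that passed in neither setting changed sign, and 0 called values reversed. The 3070 include values that passed in neither setting. Calls were lost in 10 of 712 values for lenalidomide, 194 of 736 for CRBN shRNA and 201 of 617 for the interaction. They were lost in 77 of 414 for lenalidomide in CRBN shRNA cells, 119 of 573 for infected minus uninfected and 50 of 377 for stable NT minus parental. Stable minus acute had no calls to lose. The balance of called genes turned under some alternatives. Lower genes were 47.6% after lenalidomide as reported, 54.2% with the filter at the 75th percentile, 51.3% under quantile normalization and 73.6% under median centring. In the interaction 25 of 45 differences were negative as reported, but 48 of 79 with that filter and 419 of 477 under median centring were positive, as were 151 of 269 without stable CRBN shRNA vehicle and 177 of 339 without stable NT vehicle. Among infected minus uninfected genes 22 of 40 were higher as reported, and 16 of 34 with the pseudocount at the 5th percentile, 7 of 20 without a filter, 14 of 29 under quantile normalization, 15 of 32 with all probe sets and 2 of 9 with no block. Leaving out 1 library gave from 0 of 1 (without acute NT 72 h) to 45 of 66 (without vehicle 48 h). Except where the construction shows it (fewer or more genes tested, fewer libraries), the cause was not tested. Counts are of genes past the test. With the pseudocount at the 5th percentile the interaction gave 28 and lenalidomide in CRBN shRNA cells 5, and at the 50th percentile 103 and 14, with 797 for MM1.S and -3.97 for CRBN in MM1.S. Without a filter the interaction gave 8, lenalidomide in CRBN shRNA cells 4, stable NT minus parental 0 (limma, 1020 at an unadjusted p under 0.05), infected minus uninfected 20, MM1.S 3176, and the correlation of the lenalidomide and CRBN shRNA effects 0.0297. At the 75th percentile the interaction gave 79, MM1.S 470 and the correlation 0.0957. Quantile normalization gave 2 for stable NT minus parental and a correlation of 0.0285. Median centring gave 178 for CRBN shRNA, 477 for the interaction, 0.25 for CRBN in it, 19 for lenalidomide in CRBN shRNA cells, 2 for stable minus acute and 16 for stable NT minus parental. All probe sets tested separately gave 3 for lenalidomide in CRBN shRNA cells, 0 for stable NT minus parental (1105 at an unadjusted p under 0.05) and 1871 for MM1.S. eBayes without a trend left 2853 for lenalidomide and 0 for CRBN shRNA, the interaction, lenalidomide in CRBN shRNA cells, stable NT minus parental and infected minus uninfected (1201, 1610, 618, 668 and 1667 at an unadjusted p under 0.05). CRBN with shRNA stayed at -0.85 there but did not pass (adjusted p = 0.222, within 0.00268 to 0.430 over the alternatives). With no block, lenalidomide gave 1566, CRBN shRNA 0 (595 at an unadjusted p under 0.05), CRBN -0.85 (adjusted p = 0.430) and infected minus uninfected 9. Only the 4 libraries compared gave 342 for infected minus uninfected. Against the stable NT pair alone the interaction gave 25 genes, 10 of them shared, and CRBN 0.0551. Fold thresholds of 1.5 and 3 gave 3305 and 322 for MM1.S. Of the 8 lists called for lenalidomide or CRBN shRNA, an estimated correlation left 0. The other CRBN probe set gave -0.64 with shRNA (adjusted p = 0.105), 0.0519 for stable NT minus parental, 0.0252 for infected minus uninfected and -3.01 in MM1.S. Without the acute 72 h pair CRBN shRNA gave 0 (882 at an unadjusted p under 0.05) and CRBN -0.73 (adjusted p = 0.160). Without the parental 72 h pair lenalidomide gave 2350, 2258 of them shared.

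Without 1 library at a time, counts ran from 2336 to 3832 for lenalidomide, 0 to 133 for CRBN shRNA, 0 to 339 for the interaction, 1 to 19 for lenalidomide in CRBN shRNA cells, 0 to 10 for stable minus acute, 0 to 49 for stable NT minus parental, 1 to 66 for infected minus uninfected and 8 to 13 for lists. CRBN ran from -1.04 to -0.73 with shRNA, 0.16 to 0.30 with lenalidomide, -0.11 to 0.24 in the interaction, 0.15 to 0.54 for lenalidomide in CRBN shRNA cells, 0.43 to 0.58 for stable minus acute, -0.48 to 0.0401 for stable NT minus parental and -0.40 to 0.11 for infected minus uninfected. The interaction and lenalidomide in CRBN shRNA cells could not be fitted without stable CRBN shRNA lenalidomide, stable minus acute without stable CRBN shRNA vehicle, and stable NT minus parental without stable NT lenalidomide. The filter left out genes by their mean signal, so genes with single signals under 48.7, near background, were still tested.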

Other observations

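The tests of gene families in this part were chosen only after the result was seen, on families picked from the same data. After lenalidomide in cells with intact CRBN, 12 of 14 MHC class II genes rose (median 1.28; camera adjusted p = 3.06e-06, and adjusted p = 0.211 with an estimated correlation) and 9 of 12 MHC class I genes rose and 1 fell (median 0.61; camera adjusted p = 0.00164, and adjusted p = 0.145 with an estimated correlation). Of 13 caspase and CARD genes 7 rose and 1 fell, and of 14 KLF transcription factors 8 rose and 1 fell. Of 4 SPRR genes 2 rose. Among the other families, members that fell numbered 52 of 76 for the mitochondrial ribosome (median -0.49; camera adjusted p = 2.53e-16, and adjusted p = 0.194 with an estimated correlation), 11 of 16 for RNA polymerase I and III (-0.64), 7 of 7 for the CCT chaperonin, which folds actin and tubulin (-0.57), 21 of 44 for complex I, where 2 rose (-0.27), 12 of 23 for nucleoporins (-0.36), 15 of 33 for the proteasome, where 1 rose (-0.26), 4 of 15 for aminoacyl-tRNA synthetases (-0.26, a call lost under quantile normalization, with the filter at the 75th percentile, and without stable NT vehicle or stable NT lenalidomide, where the median was 0.03) and 6 of 7 for metallothioneins, which bind metal (-0.69). Of 55 genes of the cytosolic ribosome 1 rose and 2 fell, with a median of 0.01, and of 5 S100 genes 2 rose, and neither family passed. None of these families passed with an estimated correlation, and their medians kept their direction under quantile normalization and median centring, the cytosolic ribosome aside.

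In the stable CRBN shRNA cells MHC class II genes were also higher after lenalidomide by the joint fit, 13 of 14 with a median of 1.19. Of these genes 0 passed the limma test over all genes (587 at an unadjusted p under 0.05), and 11 passed adjusted over the list alone (camera adjusted p = 3.82e-13, and adjusted p = 0.325 with an estimated correlation). Their response difference of -0.20 did not pass (camera adjusted p = 0.706), turning to 0.06 under median centring. The mitochondrial ribosome had a response difference of 0.47 (camera adjusted p = 1.81e-18, and adjusted p = 0.213 with an estimated correlation), the RNA polymerases one of 0.58 and the chaperonin one of 0.47. Camera also called response differences of 0.31 for the proteasome, 0.26 for complex I, 0.28 for nucleoporins, 0.69 for metallothioneins, -0.53 for KLF transcription factors, -0.49 for caspase and CARD genes and -1.70 for SPRR genes, and none passed with an estimated correlation (adjusted p from 0.147 to 0.234). Genes of the cytosolic ribosome were lower after lenalidomide in the stable CRBN shRNA cells, 52 of 55 with a median of -0.17 and 0 past the limma test (camera adjusted p = 0.00158, and adjusted p = 0.881 with an estimated correlation). This call was lost under quantile normalization and without acute NT or CRBN shRNA 72 h. MHC class I genes were higher there, 10 of 12 with a median of 0.23 and 0 past the limma test (camera adjusted p = 0.00269, and adjusted p = 0.325 with an estimated correlation), a call lost without stable CRBN shRNA vehicle.

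CRBN shRNA without drug gave 12 of 14 MHC class II genes above NT, with a median of 0.75, 1 past the test and 10 adjusted over the list alone (camera adjusted p = 1.96e-06, and adjusted p = 0.925 with an estimated correlation). Against uninfected vehicle cells, class II medians were -1.61 (acute NT) and -1.09 (acute CRBN shRNA) at 48 h, and -1.84 and -0.97 at 72 h. By these medians the acute CRBN shRNA cells were less lowered than NT cells, not raised above uninfected cells. Stable cells, from another experiment than the parental cells, gave medians of 0.19 (NT) and 1.40 (CRBN shRNA) against parental vehicle at 48 h. Of 55 genes of the cytosolic ribosome 50 were above NT, with a median of 0.19 and 0 past the limma test (1387 of all genes at an unadjusted p under 0.05; camera adjusted p = 1.96e-06, and adjusted p = 0.925 with an estimated correlation). That median turned to -0.0104 under quantile normalization, and the call was lost without acute NT or CRBN shRNA 72 h.

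In NT infected against uninfected cells camera called 7 more families besides MHC class II, each at adjusted p = 0.565 with an estimated correlation. Lower were the mitochondrial ribosome (72 of 76 genes, median -0.40; camera adjusted p = 7.29e-08), the cytosolic ribosome (51 of 55, -0.36; adjusted p = 9.7e-06), complex I (40 of 44, -0.36; adjusted p = 9.94e-05), the proteasome (28 of 33, -0.37; adjusted p = 0.000277), RNA polymerase I and III (12 of 16, -0.31; adjusted p = 0.0213) and metallothioneins (6 of 7, -0.72; adjusted p = 0.00127). Limma called 0 of their genes (1990 of all genes at an unadjusted p under 0.05), and 4 metallothioneins passed adjusted over the list alone. KLF transcription factors were higher (12 of 14, 0.54, 1 past the test and 6 adjusted over the list alone; camera adjusted p = 9.94e-05). The cytosolic ribosome turned to 0.00808 under quantile normalization and its call was lost without acute NT 72 h, as was that of complex I, while complex I, the proteasome and the RNA polymerases lost theirs without vehicle 72 h, and the RNA polymerases with the filter at the 75th percentile.

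In parental cells against the mean of the vehicle libraries, lenalidomide gave for MYC -1.39 at 24 h, -1.41 at 48 h and -2.10 at 72 h. For CDKN1A the values were 1.12, 2.28 and 3.02, for IFIT3 4.17, 5.37 and 6.34, and for IFI27 2.06, 4.63 and 6.31. SPRR3 gave 4.32, 3.68 and 4.91. The G1/S list had medians of 0.06, -0.33 and -0.76, and the MYC and ribosome biogenesis list -0.39, -0.78 and -1.05.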
